A study of Mus musculus with 19 samples.

How the data were processed

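Gene expression was measured in prefrontal cortex of mice killed at 20 months of age, with 1 RNA sample on each of 19 Illumina bead arrays of 25697 probes. Per the labels, the 4 genotypes were wild type (C57BL/6, n = 5), Polb+/- (n = 4), 3xTgAD (n = 6) and 3xTgAD/Polb+/- (n = 4). All 19 mice were labelled female. The labels gave no hybridisation date and no slide.

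The deposited non-normalised table held an intensity for each probe and array, averaged over beads, with no background subtraction visible (the lowest value was 30.4). Beside each intensity stood a detection p-value, which per the file headers came from the same array. GenomeStudio 1.9.0 was named in the authors' processing notes, and other steps were not stated. The authors' second table held a score for each probe and array. Recomputed z scores of the log10 intensities within each array differed from the deposited score by at most 5e-10, so that table was taken to hold z scores of each array.

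The intensities were background-corrected with the detection p-values and quantile-normalised by neqc of limma 3.58.1 (R 4.3.3, data.table version 1.17.8), with an offset of 16, and expressed as log2 intensity. Probes were kept where the detection p-value was under 0.05 on at least 4 arrays, which left 14942 of 25697. Symbols came from the platform table and were checked through Entrez identifiers for 23962 of the 23978 probes with 1 symbol. For the 2740 symbols with more than 1 kept probe, the probe with the highest mean log2 intensity stood for the gene. The 855 kept probes without a symbol stayed as themselves and are named by probe identifier. This gave 11072 genes, called so below whether named or not. Genome coordinates were not used, and the order of genes along chromosomes came from the mouse reference gene table.

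All 19 arrays entered 1 limma fit (lmFit and eBayes with default settings, 1 mean per genotype, 15 residual and 4.423 prior degrees of freedom). It gave 6 contrasts, namely 3xTgAD, Polb+/- and 3xTgAD/Polb+/- each against wild type, 3xTgAD/Polb+/- against 3xTgAD and against Polb+/-, and the interaction of the 2 genotypes. The interaction is the difference of 3xTgAD/Polb+/- from 3xTgAD minus that of Polb+/- from wild type. P-values were adjusted by Benjamini-Hochberg over the 11072 genes of each contrast, with a threshold of 0.05. All tests were two-sided. Where a gene was detected on 1 in 2 arrays of a group or fewer, its undetected arrays were set to the lowest detected signal of the array. The fold is then given as a bound, and not at all where the other group had undetected arrays too. Errors are standard errors (SE) from limma for log2 differences and standard deviations (SD) between arrays for group means.

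Before the data were examined, 24 gene lists with 698 genes were fixed, covering DNA repair, cell types, synapses and cell physiology. To them were added lists of neighbouring genes, among them the 25 nearest on each side of Polb, and 6 listed symbols were updated to current names. Of the 26 lists, 25 had at least 5 genes tested. The blood genes had 4 of 11 tested and were given no list test, and 1 further list is not reported here. Lists were tested with limma's camera at its preset correlation of 0.01, with Benjamini-Hochberg over the 150 pairs of list and contrast. Camera with an estimated correlation, fry and an exact permutation test of the list's mean on each array stood beside it. Counts of members that passed are given over all genes tested and adjusted over the list alone.

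The genes named in the text followed a rule fixed before the data were examined. In each contrast these were the genes past the threshold, at most 10 in each direction, or the 5 with the smallest p where none passed. From each list they were up to 4 members that passed, or up to 2 with the smallest p. Polb, App, Mapt and Thy1 were named throughout, and Xist and Uty served as a check of sex. Of the genes this rule allowed, those of called lists and those with larger differences are described. A gene outside the rule is said to have been chosen after its values were seen.

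The source labels wrote the age in 2 spellings, "20- month" on 11 arrays and "20 month" on 8. Each genotype held both, and the spelling was tried as a block, with fits within each spelling beside it. The headings of the intensity columns carry a code per array, and the arrays labelled 3xTgAD replicates 2 and 5 carry the same code. Whether these are 1 mouse is not stated, so both were kept, and averaging them was an added alternative. With the spelling removed, these 2 arrays correlated at 0.147, and the 14 other pairs of 3xTgAD arrays at -0.413 to -0.0819, so they were closer to each other than the other pairs and n = 6 counts arrays, not surely mice. Replicate numbers did not pair the arrays.

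The pipeline was tested on simulated data of the same group sizes and 11072 genes. In the contrasts between 2 genotypes, genes set to differ by 1 on the log2 scale were called in 83.6% to 89.6% of cases, and genes set to differ by 0.5 in 32.8% to 52.2%. For the interaction these were 70.1% and 14.9%. In each simulated contrast 67 genes were set to differ by 0.5, 67 by 1 and 66 by 2, which eases the adjustment of p-values. Where few genes differ a smaller share would be called, so these percents are not the power of the real contrasts. The shifted simulated list was called in each of the 6 contrasts, and 0 of the 20 unchanged lists were. Of the genes left unchanged, 5 to 13 were called in each contrast. The simulated genes were independent of each other, so the list test was not tried on correlated genes.

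Alternatives covered background correction, normalisation, the filter on dim probes, the probe rule, the variance model, array weights, the blocks, the arrays of each spelling alone and leaving out each array in turn. Because the deposited scores are z scores of the same intensities, the alternatives with the authors' values and with z scores are the same. Chosen after the data were examined were averaging the 2 arrays of the same code, leaving out the 2 arrays labelled 3xTgAD with Polb at the heterozygous level, leaving out 3xTgAD/Polb+/- replicate 2 under the spelling block, and the mean of the striatal markers as a covariate. A slide block could not be fitted because no slide was given. Figures were drawn with matplotlib 3.10.9. For arrays of this kind the number of arrays limits the precision.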

Results

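Expression in prefrontal cortex of 20-month-old mice was compared between 4 genotypes on 19 arrays, namely wild type (n = 5), Polb+/- (n = 4), 3xTgAD (n = 6) and their cross 3xTgAD/Polb+/- (n = 4). Polb encodes DNA polymerase beta, the gap-filling enzyme of base excision repair, and Polb+/- mice carry 1 intact copy of it. 3xTgAD mice model Alzheimer disease and carry mutant APP and MAPT transgenes. By the labels, the series asked how reduced DNA repair alters this model in old age. Between 13205 and 14379 of 25697 probes were detected on the wild type arrays, 13409 to 14396 on Polb+/-, 13232 to 14186 on 3xTgAD and 13255 to 13993 on 3xTgAD/Polb+/-. Median intensities lay at 73.1 to 109.1, 80.3 to 96, 67.7 to 91.1 and 76.2 to 91.1 in the same order. All 19 mice were labelled female. Xist, a transcript of the inactive X chromosome, had group means between 8.02 ± 0.463 (SD, n = 4, Polb+/-) and 8.31 ± 0.493 (SD, n = 4, 3xTgAD/Polb+/-). The Y-linked gene Uty had group means between 5.61 ± 0.341 (SD, n = 5, wild type) and 5.75 ± 0.11 (SD, n = 4, Polb+/-). Its probe was called detected on 4 of 5 wild type arrays and on each array of the other genotypes, at 5.16 to 6.12. Xist was at 7.26 or higher on each array. The source of the Uty signal was not tested.

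The 2 spellings of the age in the source labels separated the arrays. The 11 arrays labelled "20- month" had 14160.9 ± 200.9 probes detected (SD) and the 8 labelled "20 month" 13357.6 ± 140.2, without overlap (permutation p = 1.32e-05, the smallest that 75582 splits can give). On the first principal component, which held 26.9% of the variance, the same arrays lay at -34.38 to 0.45 and at 10.91 to 23.68. The "20- month" arrays were 3 wild type, 3 Polb+/-, 3 3xTgAD and 2 3xTgAD/Polb+/-, so values within each spelling and with the spelling as a block are given below. Within "20 month" the Polb+/- group holds 1 array, whose spread is taken to be that of the other groups.

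**Figure D1:**
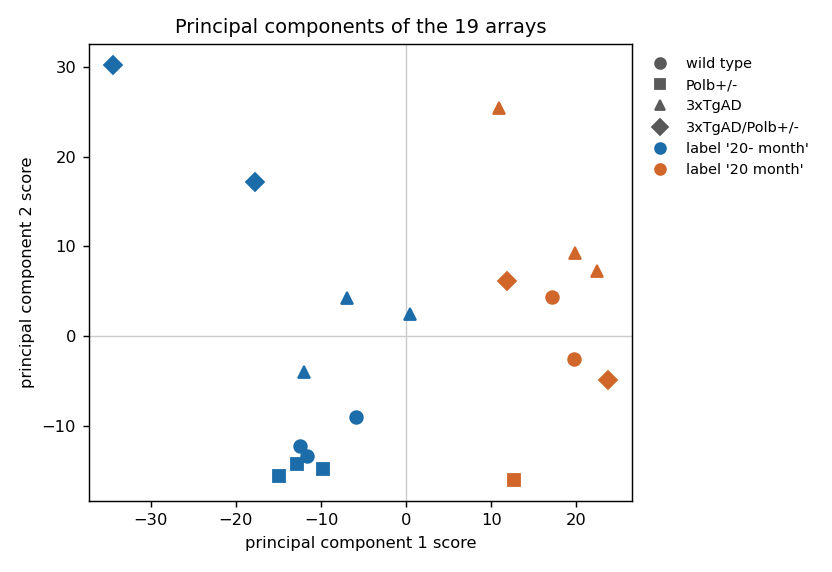
Scores of the 19 arrays on principal components 1 (x axis, 26.9% of the variance) and 2 (y axis, 18.3%) of the log2 intensities, with genotype as symbol and the spelling of the source label as colour. The "20 month" arrays lie at 10.91 or higher on component 1 and the "20- month" arrays at 0.45 or lower.

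Polb, the targeted gene, had a mean log2 intensity of 7.73 ± 0.167 (SD, n = 5) in wild type and 7.10 ± 0.159 (SD, n = 4) in Polb+/-. It was 7.34 ± 0.461 (SD, n = 6) in 3xTgAD and 7.0 ± 0.317 (SD, n = 4) in 3xTgAD/Polb+/-. Each of the 4 Polb+/- arrays lay at 7.26 or lower and each wild type array at 7.55 or higher. The log2 difference of Polb+/- from wild type was -0.63 ± 0.202 (SE, limma adjusted p = 1.0 over all genes, and 0.114 adjusted over the base excision repair list alone). It was -0.61 with the spelling as a block, -0.56 within "20- month" and -0.80 within "20 month". That of 3xTgAD/Polb+/- from 3xTgAD was -0.34 ± 0.194 (SE, limma adjusted p = 0.601). Within the spellings the latter was 0.095 for "20- month" and -0.78 for "20 month". The arrays labelled 3xTgAD replicates 4 and 6 had Polb at 6.89 and 6.64, within the range of the arrays with 1 intact copy (6.53 to 7.26). Each other array labelled 3xTgAD was higher. The level of 1 probe does not settle a genotype, and no other check of these labels was available. Both arrays also had high means of the striatal markers, given below. With that mean as a covariate the difference of Polb+/- from wild type was -0.38. Without these 2 arrays the difference of 3xTgAD/Polb+/- from 3xTgAD was -0.63 (limma adjusted p = 0.189). They were picked for their low Polb, so leaving them out had to enlarge this difference. It was -0.18 without 3xTgAD/Polb+/- replicate 3. Directions that involve 3xTgAD below include both arrays, and counts of genes and lists without them are given.

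**Figure D2:**
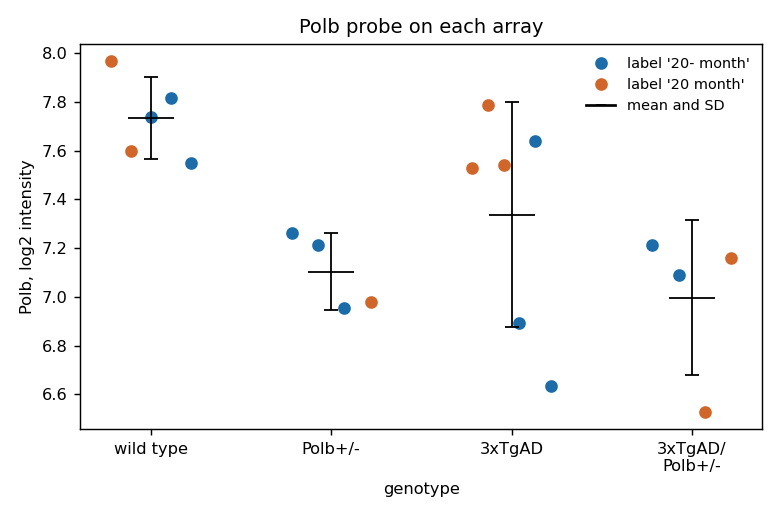
Log2 intensity of the Polb probe (y axis) on each array by genotype (x axis), coloured by the spelling of the source label, with the mean and SD of each genotype. Polb lay between 6.64 and 7.79 on the arrays labelled 3xTgAD, 2 of which fell among the arrays with 1 intact Polb copy.

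App, the gene of the amyloid precursor protein, did not pass in any contrast. Its mean log2 intensity was 13.28 ± 0.157 (SD, n = 5) in wild type and 13.38 ± 0.103 (SD, n = 6) in 3xTgAD. Mapt, the gene of tau, was 12.60 ± 0.148 (SD, n = 5) and 12.55 ± 0.181 (SD, n = 6) in these groups. The probes were designed on mouse sequence, and whether they read the human transgenes was not tested. In the limma fit of every kept probe 0 of the 4 Mapt probes passed in these comparisons with wild type. Of the 3 dimmer ones, ILMN_3107817 differed by 0.66 on the log2 scale between 3xTgAD/Polb+/- and wild type (unadjusted p = 0.00529, limma adjusted p = 0.243), ILMN_1257750 by -0.17 and ILMN_3034121 by -0.28 (both with unadjusted p over 0.05), and between 3xTgAD and wild type by 0.060, -0.17 and -0.085. Thy1, whose promoter drives the transgenes, was higher by 0.30 ± 0.184 (SE) in 3xTgAD than in wild type (limma adjusted p = 0.925). Thy1 differed by 0.63 ± 0.215 (SE) between 3xTgAD/Polb+/- and Polb+/- (limma adjusted p = 0.235).

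In the comparison of 3xTgAD with wild type, which asks what the Alzheimer genotype alone alters, Hsd17b11 was the gene that passed. Hsd17b11, a hydroxysteroid dehydrogenase of lipid droplets, rose from 9.07 ± 0.271 (SD, n = 5) to 9.96 ± 0.179 (SD, n = 6), a 1.85-fold increase, higher on each 3xTgAD array than on each wild type array. The log2 difference was 0.89 ± 0.139 (SE, limma adjusted p = 0.0403, and 0.0188 with the spelling as a block). The n of 6 counts arrays, and replicates 2 and 5 of 3xTgAD carry the same code. With these 2 averaged 0 genes passed limma, 539 had unadjusted p under 0.05, and Hsd17b11 had a difference of 0.90 and adjusted p = 0.097. The microglial gene Ly86 was lower by a difference of -0.74 ± 0.201 (SE) and passed adjusted over its list alone (adjusted p = 0.0331), not over all genes (limma adjusted p = 0.50). Among genes that passed neither way, Rsad2, an interferon-induced antiviral gene, differed by -0.77 ± 0.244 (SE), and Fgfr3, a receptor of astrocytes, by 0.62 ± 0.20 (SE). Bdnf, a neurotrophin induced by activity, differed by -0.39 ± 0.151 (SE) and Mobp, a myelin gene, by 0.47 ± 0.185 (SE). Limma p was under 0.05 for 626 genes, where 553.6 would be by chance, and the spelling block gave 2 genes. Hsd17b11 passed in 10 of the 19 fits that left out 1 array and had adjusted p = 0.241 without wild type replicate 4. The count was 0 without 3xTgAD/Polb+/- replicates 1 or 4, 3xTgAD replicates 2 or 5, Polb+/- replicates 2 or 4 or wild type replicates 3, 4 or 5. It was 9 without 3xTgAD replicate 6, 7 and 6 without wild type replicates 1 and 2, 4 without 3xTgAD replicate 3 or 3xTgAD/Polb+/- replicate 2, 3 without 3xTgAD replicates 1 or 4, and 10 without both arrays labelled 3xTgAD that had low Polb. It was 48 within "20- month", Hsd17b11 among them, and 7 within "20 month", where Hsd17b11 was not among them (0.58, limma adjusted p = 0.721).

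Of the 25 lists, camera called 3 lower in 3xTgAD than in wild type. Of the oxidative phosphorylation genes, which encode the mitochondrial respiratory chain, 62 of 69 were lower, with a median log2 difference of -0.17 (limma camera adjusted p = 3.74e-05). None of the 3 calls held with an estimated correlation, and for oxidative phosphorylation adjusted p = 0.834 with an estimated correlation. Its median was -0.18 with the spelling block, -0.090 within "20- month" and -0.31 within "20 month". Ndufb4, of respiratory complex I, differed by -0.64 ± 0.175 (SE) and Ndufb10, of the same complex, by 0.66 ± 0.218 (SE). Of the interferon response and antigen presentation genes, 17 of 21 were lower, with a median of -0.20 (camera adjusted p = 0.00539, and adjusted p = 0.776 with an estimated correlation). That median was -0.22 with the spelling block, -0.21 within "20- month" and -0.26 within "20 month". Of the cytosolic ribosomal protein genes, 34 of 42 were lower, with a median of -0.13 (camera adjusted p = 0.0468, and adjusted p = 0.889 with an estimated correlation). That median was -0.15 with the spelling block, -0.039 within "20- month" and -0.25 within "20 month". In these 3 lists 0 members passed limma over all genes tested and 0 adjusted over the list alone, with unadjusted p under 0.05 for 626 of all genes. In exact permutation tests of the array means the p was 0.0952, 0.0563 and 0.113 in the same order. Without 3xTgAD replicate 3 the medians of oxidative phosphorylation and ribosomal proteins were -0.089 and -0.036, the latter with camera adjusted p = 0.669. With the spelling block, oligodendrocyte and myelin genes were called as well (median 0.13, camera adjusted p = 0.0476, against 0.095 and 0.0811 without the block), and adjusted p = 0.834 with an estimated correlation. Without both arrays labelled 3xTgAD that had low Polb, the calls of interferon genes (-0.14, camera adjusted p = 0.198) and ribosomal proteins (-0.15, 0.0848) were lost. Striatal markers (-0.83, 1.39e-05) and immediate early genes (-0.27, 0.032) were then lower, against medians of -0.29 and -0.15 and no call with all arrays, and both had adjusted p = 0.749 with an estimated correlation. The ribosomal call held in 10 of 19 fits without 1 array, and the interferon call was lost without wild type replicate 1 (median -0.12) or replicate 2 (-0.20).

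The comparison of Polb+/- with wild type asks what loss of 1 Polb copy does on its own. With limma, 0 genes passed, and 372 had unadjusted p under 0.05, fewer than the 553.6 by chance. The smallest p belonged to Sstr1, a somatostatin receptor (limma adjusted p = 0.0725), which was at least 2.27-fold lower in Polb+/-, where it was detected on 1 of 4 arrays. Next came Twistnb, a subunit of RNA polymerase I, and Kcna5, a potassium channel, both with adjusted p = 0.198. Twistnb was at least 3.39-fold and Kcna5 at least 1.16-fold higher than in wild type, where they were detected on 1 of 5 and on 0 of 5 arrays. Zfp296 differed by -0.79 ± 0.163 (SE) and Dbpht2 by -1.94 ± 0.406 (SE). Sstr1, Twistnb and Dbpht2 all lie on chromosome 12, which held 5 of the 13 placed genes with limma p under 0.001. The cause of this nearness was not tested, so these differences are not surely due to the loss of Polb. Clic6, a chloride channel gene used as a choroid plexus marker, was higher by 1.65 ± 0.40 (SE) and passed adjusted over the list alone (adjusted p = 0.00495). The spelling block gave 0 genes (508 with unadjusted p under 0.05). The count was 3 without Polb+/- replicate 2, 2 without wild type replicate 4, 1 without Polb+/- replicate 4 or 3xTgAD replicates 2 or 4, and 15 within "20 month" (0 within "20- month"). It was 0 without both arrays labelled 3xTgAD that had low Polb (limma, 396 with unadjusted p under 0.05).

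Camera called 3 lists higher in Polb+/- than in wild type. All 11 striatal markers were higher, with a median log2 difference of 1.13 (limma camera adjusted p = 2.69e-13), and adjusted p = 0.776 with an estimated correlation. Over all genes tested 0 of them passed (limma, unadjusted p under 0.05 for 372 of all genes), and 10 were higher adjusted over the list alone. They included Tac1, the substance P precursor, at 1.47 ± 0.519 (SE), Pde1b, a calmodulin-dependent phosphodiesterase, at 0.57 ± 0.206 (SE), and Ppp1r1b, which encodes DARPP-32, at 0.88 ± 0.347 (SE). The median was 1.03 with the spelling block, 1.06 within "20- month" and 1.11 within "20 month". The mean of the list on an array was 10.15 ± 0.359 (SD, n = 4) in Polb+/- and 9.01 ± 0.971 (SD, n = 5) in wild type, where it ran from 7.78 to 9.99 (exact permutation p = 0.0635). The arrays labelled 3xTgAD with low Polb, replicates 4 and 6, had list means of 10.12 and 9.71, and the other 3xTgAD arrays had 8.10 to 8.23. Microglia markers were higher in 17 of 21, with a median of 0.17 (camera adjusted p = 0.0313, and adjusted p = 0.834 with an estimated correlation). That median was 0.14 with the spelling block, 0.16 within "20- month" and 0.18 within "20 month". Fcgr3, an Fc receptor, had the smallest p among them (0.64 ± 0.208, SE). Oligodendrocyte precursor markers were higher in 8 of 9, with a median of 0.17 (camera adjusted p = 0.0247, and adjusted p = 0.776 with an estimated correlation). That median was 0.14 with the spelling block, 0.12 within "20- month" and 0.22 within "20 month". In both lists 0 members passed limma over all genes tested and 0 adjusted over the list alone. With the spelling block, reactive astrocyte genes were called as well (median 0.13, camera adjusted p = 0.0492, against 0.10 and 0.305 without the block), and adjusted p = 0.881 with an estimated correlation. The microglia call held in 13 of 19 fits without 1 array, with adjusted p = 0.276 without wild type replicate 4 (median 0.11) and a median of 0.091 without Polb+/- replicate 4. The precursor call was lost without Polb+/- replicates 2 (0.12) or 4 (0.15) or wild type replicates 1 (0.10) or 3 (0.17).

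**Figure D3:**
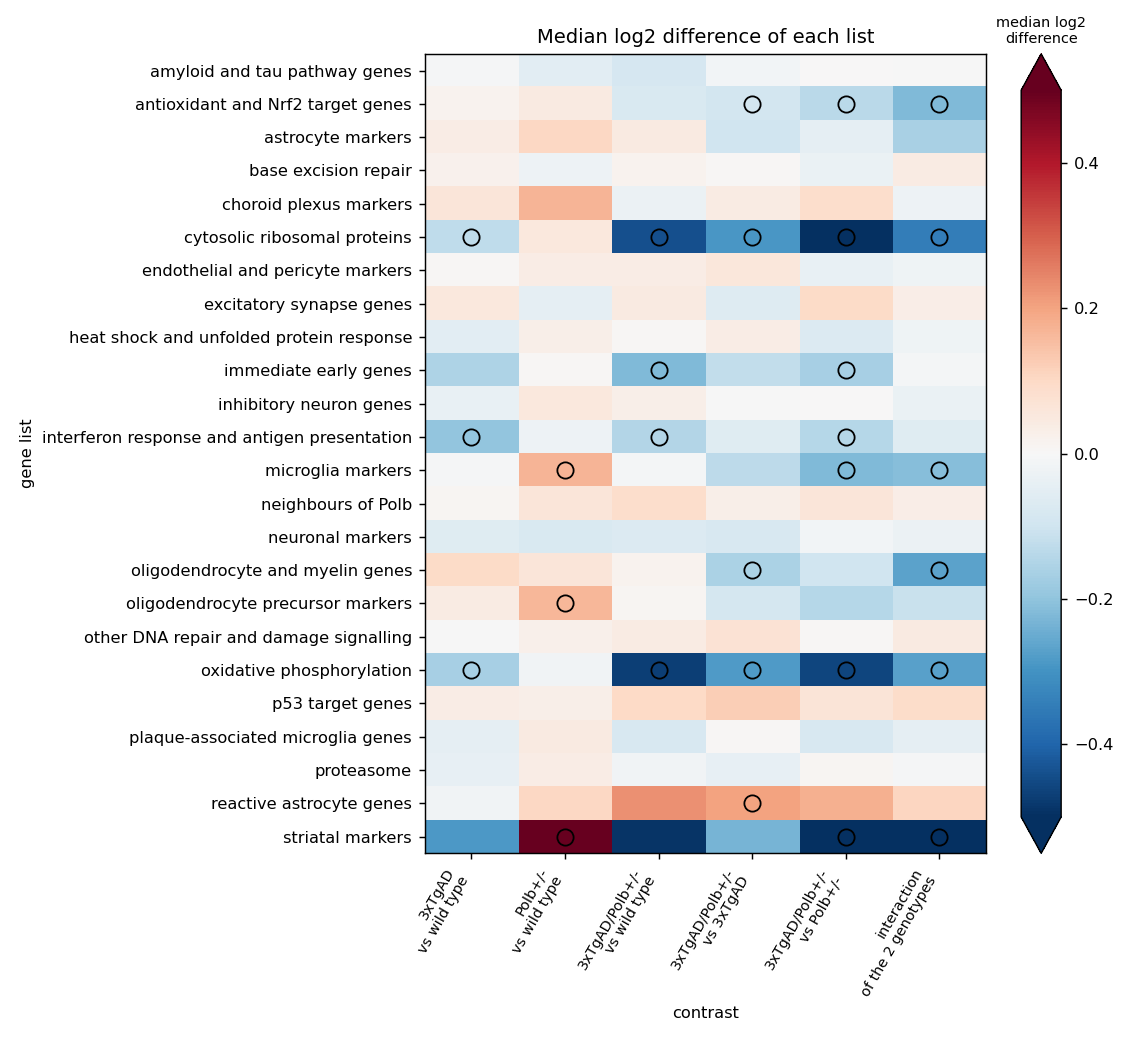
Median log2 difference (colour) of the tested members of each gene list reported here (y axis) in the 6 contrasts (x axis). Circles mark the 28 pairs with camera adjusted p under 0.05 at the preset correlation, of which 0 held with an estimated correlation; colours beyond 0.5 in size are shown at the end of the scale.

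3xTgAD/Polb+/- was compared with wild type to give the joint difference of both genotypes, and 2 genes fell. Ccnd2, which encodes cyclin D2 of the cell cycle, fell by 0.74 on the log2 scale (SE 0.104), from 9.72 ± 0.0545 (SD, n = 5) to 8.97 ± 0.145 (SD, n = 4), with limma adjusted p = 0.00823 and 0.00323 with the spelling block. Prss22, a serine protease, fell by 1.11 (SE 0.185), from 6.85 ± 0.206 (SD, n = 5) to 5.74 ± 0.339 (SD, n = 4), with limma adjusted p = 0.0454 and 0.0185 with the block. Polb itself was lower by a difference of -0.74 ± 0.202 (SE), which passed adjusted over its list of base excision repair genes alone (adjusted p = 0.0348) but not over all genes (limma adjusted p = 0.185). Nrgn, a postsynaptic calmodulin-binding protein, Sst, the peptide of somatostatin neurons, and Arc, an immediate early gene of synapses, also passed adjusted over their lists alone, with log2 differences of -0.90 ± 0.203, -0.69 ± 0.179 and -0.97 ± 0.259 (SE). Sesn1, a p53 target, was higher by 0.40 ± 0.0962 (SE) and passed in the same way. The reactive astrocyte genes Vim, Cp and Cd14 were higher adjusted over the list alone, by 0.69 ± 0.227, 0.55 ± 0.186 and 0.55 ± 0.177 (SE). The myelin genes Ppp1r14a, Opalin and Cryab were lower in the same way, at -0.83 ± 0.24, -0.92 ± 0.278 and -0.60 ± 0.186 (SE). Limma p was under 0.05 for 1464 genes, and 34 genes passed with the spelling block, both of the above among them. Without 3xTgAD/Polb+/- replicate 2 the block gave 2 genes, 1 of the above among them. Ccnd2 passed in 19 of 19 fits without 1 array and Prss22 in 7 of 19, with adjusted p = 0.168 without 3xTgAD/Polb+/- replicate 2. Counts were 324 without 3xTgAD/Polb+/- replicate 3, 6 without wild type replicate 1, 5 without 3xTgAD replicate 3 and 4 without 3xTgAD/Polb+/- replicate 1. Without most other arrays Ccnd2 alone passed. Counts were 1561 within "20- month", both genes among them, and 7 within "20 month", with neither among them (limma adjusted p = 0.494 for Ccnd2, at a difference of -0.61, and 0.426 for Prss22, at -1.17). Without both arrays labelled 3xTgAD that had low Polb, Ccnd2 was the 1 gene that passed.

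Camera called 4 lists lower in 3xTgAD/Polb+/- than in wild type. Of the oxidative phosphorylation genes, 60 of 69 were lower, with a median log2 difference of -0.47 (limma camera adjusted p = 1.55e-14), and adjusted p = 0.776 with an estimated correlation. Over all genes tested 0 passed (unadjusted limma p under 0.05 for 1464 of all genes), and 22 were lower adjusted over the list alone. Ndufa13, of complex I, differed by -0.67 ± 0.199 (SE), and the complex IV subunits Cox5a, Cox6b1 and Cox6c by -0.54 ± 0.16, -0.85 ± 0.255 and -0.94 ± 0.286 (SE). The list mean was 11.08 ± 0.514 (SD, n = 4) in 3xTgAD/Polb+/- and 11.51 ± 0.0805 (SD, n = 5) in wild type (exact permutation p = 0.0714, and 0.0167 with permutation within spellings). The median was -0.51 with the spelling block, -0.87 within "20- month" and -0.11 within "20 month". It was -0.21 without 3xTgAD/Polb+/- replicate 2, whose list mean of 10.44 was the lowest of the 19. This array stood apart in other values too, with the lowest mean correlation with the other arrays (0.967, the others 0.974 to 0.986) and scores of -34.38 and 30.23 on components 1 and 2. Of the cytosolic ribosomal protein genes, 37 of 42 were lower, with a median of -0.44 (camera adjusted p = 2.53e-09, and adjusted p = 0.79 with an estimated correlation). That median was -0.47 with the spelling block, -0.87 within "20- month" and -0.018 within "20 month", and it was -0.20 without 3xTgAD/Polb+/- replicate 2 and -0.67 without replicate 3. Rpl34 and Rps26, of the large and small subunits, differed by -0.78 ± 0.274 and -0.88 ± 0.313 (SE). Immediate early genes were lower in 18 of 21, with a median of -0.22 (camera adjusted p = 0.00909, and adjusted p = 0.776 with an estimated correlation), 1 of them adjusted over the list alone. Interferon response and antigen presentation genes were lower in 17 of 21, with a median of -0.15 (camera adjusted p = 0.00751, and adjusted p = 0.776 with an estimated correlation). Isg15, an interferon-induced ubiquitin-like protein, was at -0.76 ± 0.287 (SE), and 0 members passed over all genes or adjusted over the list alone. With the spelling block the last 2 medians were -0.22 and -0.15, within "20- month" -0.31 and -0.11, and within "20 month" -0.14 and -0.40. Without 3xTgAD/Polb+/- replicate 4 both calls were lost (medians -0.12 and -0.11). Without both arrays labelled 3xTgAD that had low Polb, striatal markers were called lower as well (median -0.49, camera adjusted p = 0.0353, and 0.125 at the same median with all arrays), and adjusted p = 0.901 with an estimated correlation. The immediate early median was -0.090 without wild type replicate 5. The interferon median was -0.31 without 3xTgAD/Polb+/- replicate 1, and its call was lost without wild type replicate 1 (-0.16).

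**Figure D4:**
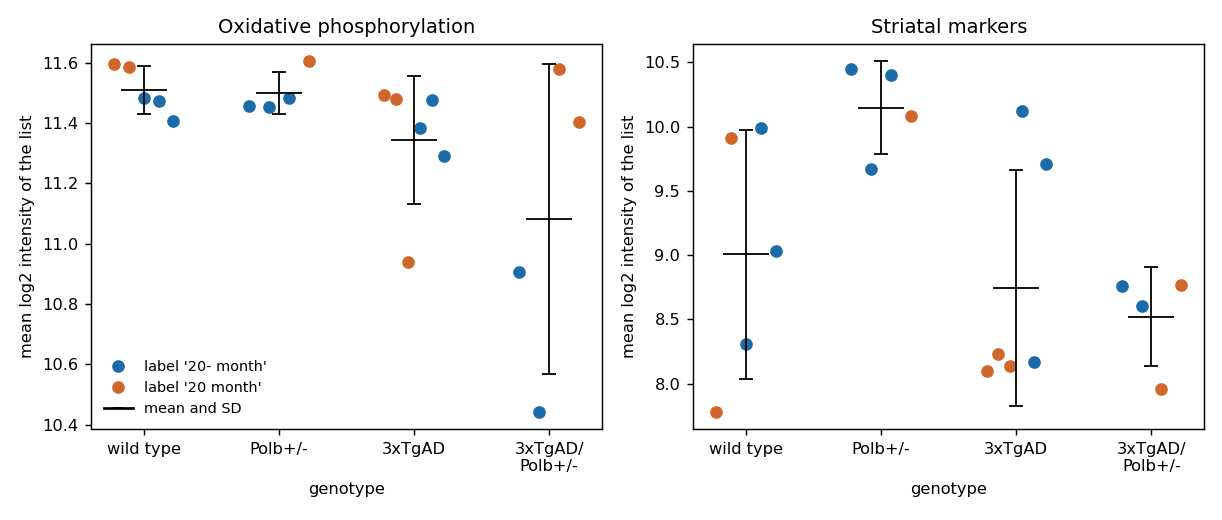
Mean log2 intensity of the oxidative phosphorylation genes (left, y axis) and the striatal markers (right, y axis) on each array by genotype (x axis), coloured by the spelling of the source label, with the mean and SD of each genotype. The oxidative phosphorylation mean of 3xTgAD/Polb+/- replicate 2 was 10.44, against 11.41 to 11.60 in wild type, and the striatal mean ran from 7.78 to 9.99 among wild type arrays.

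The question of what loss of 1 Polb copy adds in the Alzheimer background is addressed by 3xTgAD/Polb+/- against 3xTgAD. With limma 0 genes passed, 977 had unadjusted p under 0.05, and the spelling block also gave 0 genes (1562 with unadjusted p under 0.05). Prss22 had the smallest p, with a log2 difference of -1.09 ± 0.178 (SE, limma adjusted p = 0.0668, and 0.0856 with the block). Behind it were the unnamed probe ILMN_2597606 at -1.0 ± 0.194 (SE) and Prss41, a serine protease, given without a fold because it was detected on 0 of 4 3xTgAD/Polb+/- and 4 of 6 3xTgAD arrays. Ccnd2 was at -0.48 ± 0.0999 (SE) and Sphkap, a kinase anchoring protein, at 0.52 ± 0.112 (SE), each of these 4 with adjusted p = 0.266. Nrgn passed adjusted over the synaptic list alone (-0.70 ± 0.195, SE), and so did the myelin genes Ppp1r14a, Opalin and Cryab at -0.75 ± 0.231, -0.87 ± 0.267 and -0.56 ± 0.179 (SE). Counts were 3 without 3xTgAD/Polb+/- replicate 1 and 1 without 3xTgAD replicate 3, 654 within "20- month", 2 within "20 month", and 0 without both arrays labelled 3xTgAD that had low Polb.

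Camera called 4 lists lower and 1 higher in 3xTgAD/Polb+/- than in 3xTgAD. Oxidative phosphorylation genes were lower in 58 of 69, with a median log2 difference of -0.28 (limma camera adjusted p = 4.01e-08), and adjusted p = 0.834 with an estimated correlation. Ribosomal protein genes were lower in 36 of 42, with a median of -0.29 (camera adjusted p = 1.17e-06, and adjusted p = 0.834 with an estimated correlation). The spelling block left both medians at -0.28 and -0.29. Within "20- month" they were -0.82 and -0.79, and within "20 month" they had the opposite sign, 0.18 and 0.22. Without 3xTgAD/Polb+/- replicate 2 both calls were lost (medians -0.042 and -0.043). Without replicate 3 the medians were -0.48 and -0.50, and without replicate 4 that of oxidative phosphorylation was -0.44. Oligodendrocyte and myelin genes were lower in 14 of 20, with a median of -0.16 (camera adjusted p = 0.00464, and adjusted p = 0.834 with an estimated correlation), 3 of them adjusted over the list alone. That median was -0.16 with the block, 0.11 within "20- month", -0.59 within "20 month" and 0.026 without 3xTgAD/Polb+/- replicate 3, where the call was lost. It was also lost without replicate 4 (-0.12), and the median was -0.32 without replicate 1 and -0.26 without replicate 2. Antioxidant and Nrf2 target genes were lower in 19 of 23, with a median of -0.093 (camera adjusted p = 0.033, and adjusted p = 0.831 with an estimated correlation). That median was -0.093 with the block, -0.24 within "20- month" and 0.10 within "20 month". The call was lost without 3xTgAD/Polb+/- replicate 2 (-0.015) or 3xTgAD replicate 4 (-0.068), and the median was -0.15 without 3xTgAD/Polb+/- replicate 3. Mt1, a metallothionein, was at -0.49 ± 0.229 (SE). Reactive astrocyte genes were higher in 15 of 17, with a median of 0.20 (camera adjusted p = 0.0452, and adjusted p = 0.834 with an estimated correlation). Cp, ceruloplasmin, was at 0.50 ± 0.179 (SE) and Vim, the filament protein vimentin, at 0.43 ± 0.218 (SE). The astrocyte median was 0.20 with the block, 0.11 within "20- month" and 0.30 within "20 month". That call held in 12 of 19 fits without 1 array, with adjusted p = 0.648 at a median of 0.23 without 3xTgAD/Polb+/- replicate 3, and the median was 0.13 without 3xTgAD replicate 6 and 0.31 without replicate 1. Without both arrays labelled 3xTgAD that had low Polb, the myelin (-0.13), antioxidant (-0.092) and astrocyte (0.11) calls were lost. Apart from the 3 myelin genes, 0 members of these 5 lists passed limma over all genes or adjusted over the list alone (unadjusted p under 0.05 for 977 of all genes). Exact permutation p-values of the array means were between 0.152 and 0.333.

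Between 3xTgAD/Polb+/- and Polb+/-, which gives the difference of the Alzheimer genotype when 1 Polb copy is missing, 10 genes passed, 5 higher and 5 lower. Dbpht2 rose from 7.15 ± 1.4 (SD, n = 4) to 9.52 ± 0.215 (SD, n = 4), by 2.37 ± 0.428 (SE) on the log2 scale with limma adjusted p = 0.0386. Its Polb+/- arrays split into 2 at 5.87 and 6.02 and 2 at 8.12 and 8.59. Sstr1, detected on 1 of 4 Polb+/- arrays, was at least 2.11-fold higher (limma adjusted p = 0.0396). Dbpht2 and Sstr1 were also lower in Polb+/- than in wild type, though neither passed there, Dbpht2 by a difference of -1.94. Sstr1 had a mean of 6.57 in wild type and 6.47 in 3xTgAD/Polb+/-, so its Polb+/- arrays stood apart from both. Vps33a, of the vesicle tethering machinery, Egln3, an oxygen-sensing prolyl hydroxylase, and Frmd3 rose by 0.86 ± 0.147, 0.78 ± 0.147 and 0.68 ± 0.123 (SE). Lypd1, which binds nicotinic receptors, fell from 10.42 ± 0.258 to 9.43 ± 0.331 (SD, n = 4 each, limma adjusted p = 0.0337). The unnamed probes ILMN_2597606 and ILMN_1228752 fell by 1.31 and 0.76. In 3xTgAD/Polb+/- they also differed from wild type, by -1.09 and -0.62 (limma adjusted p = 0.067 and 0.0853). The cardiac myosin light chain gene Myl2 and the histone gene H4c18 were not detected on the 3xTgAD/Polb+/- arrays, and were at least 1.52-fold and at least 1.46-fold lower there. Adjusted p of the 10 lay between 0.0337 and 0.0491. Limma p was under 0.05 for 1343 genes, and all 10 genes also passed with the spelling block, which gave 24. Without 3xTgAD/Polb+/- replicate 2 the block gave 4 genes, 2 of the 10 among them. With the mean of the striatal markers as a covariate 1 gene passed and 0 of the 10 did. The differences were then 0.71 ± 0.182 for Vps33a, 2.0 ± 0.535 for Dbpht2, 0.57 ± 0.173 for Egln3, 0.52 ± 0.149 for Frmd3, -0.83 ± 0.195 for Lypd1, -1.19 ± 0.272 for ILMN_2597606 and -0.61 ± 0.168 for ILMN_1228752 (SE). They kept their direction, were smaller in size than without it, and had an SE 1.18 to 1.28 times as large. The other 3 had a group near background, so the size of their differences is not settled with or without the covariate. As measured, H4c18 and Sstr1 were also smaller, and Myl2 was larger in size (-1.35, against -1.13 without the covariate). Counts were 0 without Polb+/- replicates 1 or 3, 3xTgAD/Polb+/- replicates 1 or 2, 3xTgAD replicate 5 or wild type replicate 3, and 3 or 4 without 3xTgAD/Polb+/- replicate 4, 3xTgAD replicates 3 or 6 or wild type replicate 5. They were 260 without 3xTgAD/Polb+/- replicate 3, 31, 20 and 15 without wild type replicates 1, 4 and 2, 23 without 3xTgAD replicate 4, 6 without 3xTgAD replicate 1 and 27 without both arrays labelled 3xTgAD that had low Polb, all 10 among the 27. They were 1272 within "20- month", with 9 of the 10 among them, and 12 within "20 month", with 1 of the 10 among them.

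Camera called 7 lists lower in 3xTgAD/Polb+/- than in Polb+/-. All 11 striatal markers were lower, with a median log2 difference of -1.75 (limma camera adjusted p = 1.56e-10), and adjusted p = 0.776 with an estimated correlation. Over all genes 0 of them passed (unadjusted limma p under 0.05 for 1343 of all genes), and 10 were lower adjusted over the list alone, among them Drd1, the dopamine D1 receptor (-2.10 ± 0.551, SE), and Tac1 (-2.01 ± 0.547, SE). The median was -1.59 with the spelling block, -1.50 within "20- month" and -1.81 within "20 month", and the exact permutation p was 0.0286, the smallest that 70 splits can give. Oxidative phosphorylation genes were lower in 59 of 69 (median -0.46, camera adjusted p = 1.41e-13, and adjusted p = 0.776 with an estimated correlation), 2 of them adjusted over the list alone, Ndufb2 (-1.19 ± 0.288, SE) and Sdhc (-0.65 ± 0.169, SE). Ribosomal protein genes were lower in 37 of 42 (median -0.50, camera adjusted p = 7.06e-12, and adjusted p = 0.776 with an estimated correlation). These 2 medians were -0.51 and -0.56 with the block, -0.91 and -0.94 within "20- month", -0.11 and -0.12 within "20 month", and -0.18 and -0.24 without 3xTgAD/Polb+/- replicate 2. Microglia markers were lower in 17 of 21 (median -0.22, camera adjusted p = 0.00201, and adjusted p = 0.776 with an estimated correlation), with Trem2, a microglial receptor, at -0.59 ± 0.193 (SE). That call was lost without 3xTgAD/Polb+/- replicate 3 (-0.15), and the median was -0.34 without Polb+/- replicate 3. Antioxidant genes were lower in 18 of 23 (median -0.14, camera adjusted p = 0.0208, and adjusted p = 0.79 with an estimated correlation), and the call was lost without 3xTgAD/Polb+/- replicate 2 (-0.035) or Polb+/- replicate 4 (-0.14). The antioxidant median was -0.23, -0.24 and -0.23 without 3xTgAD/Polb+/- replicates 1, 3 and 4. Interferon response and antigen presentation genes were lower in 17 of 21 (median -0.14, camera adjusted p = 0.0275, and adjusted p = 0.79 with an estimated correlation), 1 of them adjusted over the list alone, Bst2, which tethers virions (-0.91 ± 0.258, SE). That call was lost without 3xTgAD/Polb+/- replicates 2 (-0.20) or 4 (-0.099) or Polb+/- replicate 1 (-0.16), and the median was -0.27 without 3xTgAD/Polb+/- replicate 1. Immediate early genes were lower in 16 of 21 (median -0.17, camera adjusted p = 0.0341, and adjusted p = 0.776 with an estimated correlation), with Nr4a2, a nuclear receptor, at -0.86 ± 0.263 (SE). That call was lost with the spelling block (-0.090, camera adjusted p = 0.174) and held in 14 of 19 fits without 1 array, with a median of -0.028 without 3xTgAD/Polb+/- replicate 4, -0.097 without replicate 1, -0.27 without replicate 2 and -0.31 without replicate 3. For microglia, antioxidant, interferon and immediate early genes in that order, the block gave -0.33, -0.20, -0.16 and -0.090. Within "20- month" they were -0.17, -0.32, -0.16 and -0.20, and within "20 month" -0.52, -0.054, -0.20 and -0.036.

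The interaction asks whether loss of 1 Polb copy differed between the 3xTgAD and wild type backgrounds. With limma 0 genes passed, 357 had unadjusted p under 0.05, where 553.6 would be by chance, and the spelling block gave 0 genes (616 with unadjusted p under 0.05). The smallest p belonged to Egln3, at 0.87 ± 0.194 (SE, limma adjusted p = 1.0), followed by ILMN_2597606 at -1.22 ± 0.28 (SE), Lypd1 at -0.87 ± 0.208 (SE), Mboat2, a lysophospholipid acyltransferase, at -1.86 ± 0.472 (SE), and Dbpht2 at 2.16 ± 0.563 (SE). The choroid plexus genes Clic6, at -1.76 ± 0.555 (SE), and Ttr, the carrier transthyretin, detected on 2 of 4 3xTgAD/Polb+/- arrays, passed adjusted over their list alone. The count was 0 without both arrays labelled 3xTgAD that had low Polb (limma, 393 with unadjusted p under 0.05), 151 within "20- month" and 1 within "20 month".

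Camera called 6 lists lower for the interaction. Striatal markers were lower in 11 of 11 (median -1.32, limma camera adjusted p = 7.35e-10, and adjusted p = 0.776 with an estimated correlation). Ribosomal protein genes were lower in 39 of 42 (median -0.34, camera adjusted p = 2.52e-08, and adjusted p = 0.79 with an estimated correlation). Oxidative phosphorylation genes were lower in 56 of 69 (median -0.27, camera adjusted p = 2.19e-06, and adjusted p = 0.834 with an estimated correlation). Oligodendrocyte and myelin genes were lower in 18 of 20 (median -0.27, camera adjusted p = 0.000224, and adjusted p = 0.79 with an estimated correlation), with Mobp at -0.78 ± 0.284 (SE). Antioxidant genes were lower in 20 of 23 (median -0.22, camera adjusted p = 0.00538, and adjusted p = 0.776 with an estimated correlation). Microglia markers were lower in 17 of 21 (median -0.21, camera adjusted p = 0.0244, and adjusted p = 0.834 with an estimated correlation). In these 6 lists 0 members passed limma over all genes or adjusted over the list alone (unadjusted p under 0.05 for 357 of all genes). Without both arrays labelled 3xTgAD that had low Polb, all 6 calls held, with the striatal median at -0.74 and the antioxidant median at -0.14. In the order given, the medians with the spelling block were -1.19, -0.36, -0.32, -0.25, -0.21 and -0.19. Within "20- month" they were -1.77, -0.86, -0.85, -0.036, -0.41 and -0.051, and within "20 month" -1.12, 0.11, 0.15, -0.56, -0.023 and -0.42, so ribosomal proteins and oxidative phosphorylation had opposite signs in the 2 spellings. Without 3xTgAD/Polb+/- replicate 2 the calls of ribosomal proteins (-0.11), oxidative phosphorylation (-0.027) and antioxidant genes (-0.062) were lost. Without replicate 3 those of myelin genes (-0.081) and microglia markers (-0.043) were lost, and the ribosomal and oxidative phosphorylation medians were -0.54 and -0.47. The myelin median was -0.17 without wild type replicate 3, the oxidative phosphorylation median -0.42 without 3xTgAD/Polb+/- replicate 4, and the microglia call held in 12 of 19 fits without 1 array.

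Camera made no call in the 6 contrasts for the lists that follow, among them those nearest to the function of Polb. Base excision repair genes, with 21 tested, had median log2 differences of -0.024 for Polb+/- against wild type (limma camera adjusted p = 0.783) and 0.0055 for 3xTgAD/Polb+/- against 3xTgAD (camera adjusted p = 0.901). For 3xTgAD/Polb+/- against wild type their median was 0.018, with Polb the 1 member that passed adjusted over the list alone. In that comparison the medians were 0.042 for other DNA repair and damage signalling, 0.10 for p53 target genes (camera adjusted p = 0.187) and 0.090 for the neighbours of Polb. Amyloid and tau pathway genes had -0.085, plaque-associated microglia genes -0.079, proteasome genes -0.018, and heat shock and unfolded protein response genes 0.0060. Excitatory synapse genes had 0.046, inhibitory neuron genes 0.030, neuronal markers -0.068, astrocyte markers 0.044, endothelial and pericyte markers 0.039 and choroid plexus markers -0.028. Between 3xTgAD/Polb+/- and Polb+/-, some members of these lists were lower adjusted over the list alone, namely Clic6 (-1.88 ± 0.422, SE), Ttr (at least 6.11-fold, and at least 3.33-fold without Polb+/- replicate 2) and Lpl, a lipase of plaque-associated microglia (-0.84). Of the 150 pairs of list and contrast, 28 were called with the preset correlation, 29 with the spelling as a block, and 26 without both arrays labelled 3xTgAD that had low Polb, 23 of the 28 among them. The count was 0 with an estimated correlation (6 with unadjusted p under 0.05), 0 with fry, and 0 of 125 with exact permutation (3 with unadjusted p under 0.05). With groups this small, the exact test cannot give a p small enough for 1 list alone to pass that adjustment. Its count was thus nearly fixed in advance and says little about the calls.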

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

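The tests of the batch with the spelling as a block, of striatal tissue, of Polb loss acting alike in both backgrounds, of chromosome segments, of the splits of the 3xTgAD/Polb+/- and Polb+/- arrays and of splits within the spellings, and the values without 3xTgAD replicates 4 and 6 or with the arrays of the same code averaged, were chosen after the results were seen, as was the standard error set beside the share of genes with the same sign.

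In 10 of 176 groups of 4 to 6 arrays, the highest or lowest array stood far from the others by Dixon's test, which chance does in about 1 in 20 groups (8.8 of 176). Among genes these were Hsd17b11 in 3xTgAD replicate 4 (10.32), Egln3 in Polb+/- replicate 2 (7.20), Myl2 in 3xTgAD replicate 1 (6.08), Ccnd2 in 3xTgAD replicate 1 (9.76), and Sstr1 in wild type replicate 4 (6.0) and Polb+/- replicate 2 (5.88). Among list means they were base excision repair in Polb+/- replicate 4 (7.66), plaque-associated microglia genes in wild type replicate 2 (9.15), and ribosomal proteins (12.12) and oxidative phosphorylation (10.94) in 3xTgAD replicate 3.

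In 6 lists the difference linked to Polb loss differed between the 3xTgAD and wild type backgrounds by the interaction term (limma camera). The median differences were -1.32 for striatal markers (-0.74 without the arrays labelled 3xTgAD replicates 4 and 6), -0.34 for ribosomal proteins, -0.27 for oxidative phosphorylation, -0.27 for oligodendrocyte and myelin genes, -0.22 for antioxidant genes and -0.21 for microglia markers. None of these 6 calls held with an estimated correlation, where the lowest adjusted p was 0.776.

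Oxidative phosphorylation genes were lower in 3xTgAD/Polb+/- than in wild type, with a median of -0.47 (SE 0.178). Each SE beside a list median in this section is that of the difference between groups in the arrays' list means, not of the median. A batch that follows the spelling is argued against as the whole cause, since the median was -0.51 (SE 0.166) with the spelling as a block, and so is a shift of all bright probes, since 0% of 10000 random lists of the same intensity had a median as low (the lowest was -0.12). Dependence on 3xTgAD/Polb+/- replicate 2 could not be settled, because the median without it was -0.21 (SE 0.14), and the medians within the spellings were -0.87 and -0.11. The spread of the list between arrays of 1 genotype stays open, with an exact permutation p of 0.0714 over all arrays. Within the spellings it was 0.0167, the smallest that 60 splits can give. The latter had adjusted p = 0.444 over the 125 pairs tested so, an adjustment that 1 list alone could not pass. The genotype may contribute, and these data do not separate it from that spread.

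Striatal markers were higher in Polb+/- than in wild type, with a median of 1.13 (SE 0.514). A batch that follows the spelling is argued against as the whole cause, since the median was 1.03 (SE 0.492) with the spelling as a block, a test chosen later. The value within "20- month", 1.06 (SE 0.612), passed the bound set beforehand by less than its SE, so it could not decide. The median of 1.11 within "20 month" rests on 1 Polb+/- array. More striatal tissue in some dissected pieces is a candidate explanation, since deviations of the 11 members from their group means went together (median correlation 0.854, lowest of 55 pairs 0.31). The probes of Ppp1r1b and Pde1b, the brightest of the members named above, had Polb+/- means of 12.42 and 12.43, though levels of different probes are not on 1 scale. Loss of 1 Polb allele acting alike in both backgrounds stays open, because 3xTgAD/Polb+/- against 3xTgAD gave -0.23 (SE 0.495), and 0.39 (SE 0.421), the opposite sign, without the arrays labelled 3xTgAD replicates 4 and 6.

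Of the 24 genes with limma p under 0.001 in 3xTgAD against wild type, 23 had a place on the chromosomes of GRCm38.p6, and they made 8 pairs 6 to 100 genes apart, as many as in 0.34% of 10000 random gene sets (2.18 pairs on average). Segments of another strain's chromosomes may be carried in the 3xTgAD line, which this value allows and no genotypes measured here test. The same percent was 0.01 for Polb+/- against wild type, which shares the wild type arrays, and 23.5, 30.6 and 0.21 for 3xTgAD/Polb+/- against wild type, 3xTgAD and Polb+/-, and 2.33 for the interaction, so nearness from a source other than 3xTgAD segments stays open. Whether the double mutant shares the difference could not be settled. Of the 24 genes, 14 (58.3%, SE 10.1) had the same sign and p under 0.05 in 3xTgAD/Polb+/- against Polb+/-. This did not reach the bound of 60% set beforehand. Of all genes, 6.07% had such a p for a given sign. The 2 contrasts share no array, but both use the residual variance of each gene over all arrays. Genes picked for small p tend to have a small variance, so 6.07% is not the share to expect of them without sharing. These 14 genes were reached in 1 of the 70 splits of the 8 arrays, the real split (exact p = 0.0143, the smallest they can give, highest other 7). So were the 9 with the spelling block. The 24 genes were picked for small p under the real groups, and other splits tend to widen their spread. This count therefore favours the real split and decides nothing. The sign alone does not use the spread, and 23 of the 24 shared it (21 with the block). It was reached in 3 of the 70 splits (exact p = 0.0429), 2 of the 30 within the spellings, and 6 of the 70 with the block (exact p = 0.0857). The sign thus does not settle the question.

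The same arrays were split into groups of the same sizes, and the counts of splits here and below include the real split. As many genes passed in 5 of 100 splits for 3xTgAD against wild type (real value 1, highest other 462). This was so in 10 of 100 for 3xTgAD/Polb+/- against wild type (2, 1025) and 3 of 35 against Polb+/- (10, 15). The splits thus did not allow chance to be excluded. Where the real count was 0 every split reaches it, and the splits say nothing about chance. That was so for Polb+/- against wild type (100 of 100, highest other 2), 3xTgAD/Polb+/- against 3xTgAD (100 of 100, highest other 527) and the interaction (100 of 100, highest other 3). Splitting by the spelling of the label gave 1109 genes among the 3xTgAD and wild type arrays and 1025 among the 3xTgAD/Polb+/- and wild type arrays, which points to a structure of the samples. With splits made within the spellings, as many genes passed in 1 of 100 for 3xTgAD against wild type (highest other 0), 1 of 60 for 3xTgAD/Polb+/- against wild type (highest other 1) and 1 of 30 against Polb+/- (highest other 1). With the spelling as a block the real counts were 2, 34 and 24, and 5, 2 and 4 without 3xTgAD/Polb+/- replicate 2. The former were again reached in 1 of 100, 1 of 60 and 1 of 30 such splits (highest others 1, 9 and 1). These splits differ from those over all arrays and were chosen after the results were seen, so chance is not taken as excluded. Those for 3xTgAD against wild type also count the 3xTgAD arrays of the same code separately, and with these averaged 0 genes passed limma (539 with unadjusted p under 0.05). For 3xTgAD/Polb+/- against 3xTgAD a split within the spellings gave up to 371 genes, and up to 939 with the spelling as a block. This points to a structure other than the spelling.

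As many lists were called in 80 of 100 (3, 9), 63 of 100 (3, 8), 74 of 100 (4, 10), 44 of 100 (5, 7), 7 of 35 (7, 9) and 20 of 100 splits (6, 8), for 3xTgAD, Polb+/- and 3xTgAD/Polb+/- against wild type, 3xTgAD/Polb+/- against 3xTgAD and against Polb+/-, and the interaction, so chance was not excluded for any count of lists. Within the spellings these were 91 of 100, 35 of 60, 47 of 60, 46 of 100, 6 of 30 and 24 of 100. In the same order limma reported 626, 372, 1464, 977, 1343 and 357 genes at unadjusted p under 0.05.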

How the results depend on the processing

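Averaging the arrays of the same code, leaving out the arrays labelled 3xTgAD replicates 4 and 6, the spelling block without 3xTgAD/Polb+/- replicate 2, and the striatal covariate were chosen after the data were examined, as were the alternatives for the gene lists other than camera with an estimated correlation, fry and the 2 blocks.

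The numbers of genes past the threshold were 1 (3xTgAD against wild type), 0 (Polb+/- against wild type), 2 (3xTgAD/Polb+/- against wild type), 0 (against 3xTgAD), 10 (against Polb+/-) and 0 (interaction), and limma gave 372, 977 and 357 genes at unadjusted p under 0.05 where none passed. Below, only counts more than 1.5 times away are given. For 3xTgAD against wild type the count was 2 with the authors' values and the z scores, 0 with no filter, every probe, only the groups of the contrast or the same-code arrays averaged, 58 with arrayWeights, 2 with the spelling block, 48 within "20- month", 7 within "20 month", 3 with the replicate block, 10 without 3xTgAD replicates 4 and 6, 5 with the block without 3xTgAD/Polb+/- replicate 2 and 3 with the striatal covariate. Leaving out 1 array gave 0 to 9. For Polb+/- against wild type it was 8 with arrayWeights, 15 within "20 month" and 1 with the same-code arrays averaged, and leaving out 1 array gave 0 to 3.

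For 3xTgAD/Polb+/- against wild type it was 6 with no background correction or with trend and robust, 1 with the authors' values, the z scores, every probe or without 3xTgAD replicates 4 and 6, 5 with probes detected on all 19 arrays, 0 with only its groups or the replicate block, 1309 with arrayWeights, 34 with the spelling block, 1561 within "20- month", 7 within "20 month" and 4 with the striatal covariate. With the spelling block and without 3xTgAD/Polb+/- replicate 2 the 34 fell to 2. Leaving out 1 array gave 1 to 324, the highest without 3xTgAD/Polb+/- replicate 3. For 3xTgAD/Polb+/- against 3xTgAD it was 1 with probes detected on all arrays, 581 with arrayWeights, 654 within "20- month" and 2 within "20 month", and leaving out 1 array gave 0 to 3.

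For 3xTgAD/Polb+/- against Polb+/- it was 6 with normexp or no background correction, 4 with the authors' values, the z scores or trend and robust, 0 with no filter or the replicate block, 2 with every probe, 56 with only its groups, 1233 with arrayWeights, 24 with the spelling block, 1272 within "20- month", 5 with the same-code arrays averaged, 27 without 3xTgAD replicates 4 and 6, 4 with the block without 3xTgAD/Polb+/- replicate 2 and 1 with the striatal covariate. Leaving out 1 array gave 0 to 260, the highest without 3xTgAD/Polb+/- replicate 3. For the interaction it was 3 with arrayWeights, 151 within "20- month" and 1 within "20 month", and 0 without each array in turn. The causes of these shifts were not tested.

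Polb was lower in Polb+/- than in wild type under each alternative, by -0.68 to -0.58 without 1 array. Polb differed by -0.48 with normexp, -0.51 with no background correction, -0.50 with the authors' values and -0.80 within "20 month". With the striatal covariate Polb differed by -0.38, against -0.63 without it. In 3xTgAD/Polb+/- against 3xTgAD its difference was 0.095 within "20- month" and -0.78 within "20 month", and -0.48 to -0.18 without 1 array; the cause was not tested, and the 2 arrays labelled 3xTgAD with low Polb are both "20- month".

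Of 150 pairs of list and contrast 28 were called, 16 with arrayWeights, 21 to 35 without 1 array, and 0 with an estimated correlation or fry. The striatal covariate gave 18 of 144 pairs, 14 of them among the 28, with 10 calls lost and 1 of opposite direction. The striatal list, with 3 of the 28 calls, could not be tested with it. Exact permutation, over all arrays or within spellings, gave 0 of 125 pairs, where 1 list alone could not pass. With arrayWeights the medians of oligodendrocyte and myelin genes in 3xTgAD/Polb+/- against 3xTgAD (0.18) and the interaction (0.018), and of interferon genes against Polb+/- (0.0068), had the opposite sign. Within "20- month" the oligodendrocyte median against 3xTgAD was 0.11, and without 1 array it ran from -0.32 to 0.026. Within "20 month", antioxidant genes, ribosomal proteins and oxidative phosphorylation against 3xTgAD were at 0.10, 0.22 and 0.18, and the last 2 in the interaction at 0.11 and 0.15. With the striatal covariate the oligodendrocyte interaction was at 0.018. With the alternative background corrections and scalings the 28 medians kept their sign. The causes were not tested.

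Values for single genes and lists were compared with the reported ones, apart from the fits without 1 array. Under alternatives chosen before the data were examined, 4794 left the call as it was, 266 ended a call, 215 added one and 156 moved. Among those chosen later these were 3659, 206, 59 and 115, and 10 calls had the opposite direction. Where there was no call, the direction was not always kept. The oxidative phosphorylation median in Polb+/- against wild type was -0.016, and 0.025 with the spelling block. A slide block was not run because no slide is given. Probes near background limit what can be seen, as for Myl2 and H4c18, detected on 0 of 4 arrays of 3xTgAD/Polb+/-.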
